A study of Mus musculus with 8 samples.

How the data were processed

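The samples were subcutaneous tumours of mice, taken apart mechanically with a tumour dissociation kit and profiled with the 10x Chromium single cell 3' method, per the labels' protocols. The deposited files hold raw UMI counts per gene and cell barcode, made with Cell Ranger and mm10 per the submitters' processing notes, and per the file headers with version 5.0.0 for C1, C2 and U1 and 6.0.2 for the other 5 libraries. The annotation release, the cell calling settings and whether introns were counted are not given in the sources used here. The matrices hold, with at least 500 UMIs in every barcode, 5208 barcodes in U3 to 14393 in U4. Of 32285 gene IDs, 32235 were found in the GENCODE M21 annotation of GRCm38, from which the printed coordinates come, and 50 were not. Library depth bounds the precision, with 75779540 to 155494977 UMIs per library, and Wilson intervals cover counting error only.

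Cells were kept with at least 300 genes and 500 UMIs and under 20% mitochondrial UMIs. Doublets were removed per library as the cells with the highest Scrublet scores, 0.8% per 1000 barcodes, which took 6765 cells (4.16 to 11.5% per library), while the automatic threshold of Scrublet marked 0 to 3.23%. Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 principal components and 4 neighbours from each library gave the graph for Leiden clustering at resolution 1.5 (36 clusters). Clusters were named from 28 fixed marker lists, with at least 3 markers and all but 1 of the list over 2-fold above the baseline over clusters and a mean log2 fold of at least 2.5. T and NK cells and dendritic cells were clustered again, each set at resolution 1, and a sub-cluster name needed that mean and 3 such markers. No name went to a cluster or sub-cluster under 30 cells, over 50% doublets, or with few UMIs and none of its markers among its top 10 genes, nor to a sub-cluster led by more markers (2 or more) of another class than of its own. Clusters that no list named, with Ptprc under 50 CPM and more UMIs per cell than the median of their libraries, form the Ptprc-low class, and the rest stayed unnamed (1.98% of kept cells in C, 1.56% in U). The graph, the resolutions and the naming bounds were set over several rounds after seeing the data. The last of these changes followed a first gene test under older names, which also called 0 genes by edgeR in each of the 10 sums. Cell classes are names rebuilt from markers, not a deposited annotation.

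Shares of cells were compared by 2-sided exact permutation tests over the libraries, with Benjamini-Hochberg adjustment over 11 classes, 5 subsets of T and NK cells and 7 subsets of mononuclear phagocytes. For genes, counts were summed per library over all kept cells and within each class. A library entered a class with at least 30 cells and a class was tested with at least 3 such libraries per group, so that C4 (19 cells) is out of the CD4 T cell sums, U3 (27 cells) out of those of regulatory T cells and U3 (17 cells) out of those of endothelial cells. Dendritic sums hold the 1476 cells of named dendritic subsets. The sums were tested with edgeR's quasi-likelihood test (filterByExpr, TMM, robust fit, adjusted p under 0.05). Of 38 gene lists, those with at least 5 tested members were tested per sum with limma's camera on log2 CPM (prior count 2, preset correlation 0.01, adjusted over 305 pairs of list and sum), besides camera with an estimated correlation and fry. Adjusted p-values of genes come from edgeR or, where named, DESeq2, and those of lists from limma. Free RNA was described with 7 macrophage markers and members under 5% of their macrophage level.

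Groups, tests, gene lists, cell type markers and the first set of alternatives were fixed before the data were examined. The rule for named genes took the genes with the largest change past the threshold, and where fewer than 3 pass in a sum, as in each of the 10, the 5 with the smallest p, named as not past it. That last part does not exclude predicted genes (names with Gm or Rik), a reading chosen after the genes were seen. Fixed panels for T and NK cells, for macrophages and monocytes and for tumour-like cells were printed whatever their p. The 3 members with the smallest p given for 20 pairs of list and class, that rule and those pairs were chosen after seeing the data, and 1 of these members is not reported here.

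Alternatives covered a stricter cell filter (500 genes, 1000 UMIs, under 10% mitochondrial), no doublet removal, Leiden resolution 2.5, shares among immune cells, edgeR on cell counts, DESeq2 size factors, the DESeq2 Wald test, no low-count filter, at least 100 cells per library and class, leaving out genes under 5% of their level in the class with the most, the replicate number as a block and leaving out each library. Chosen after seeing the data were the Cell Ranger version as a term, the libraries of each version alone, clustering with 20 neighbours not balanced over libraries and CD8 T cells without an interferon-led sub-cluster. No 2 libraries of a group agreed within sampling noise (smallest chi-square per degree of freedom 56.0, C1 and C2). On simulated counts with 200 changed genes and 20 changed lists, 1.92 to 7.84% of calls fell on unchanged genes. Tools were Python 3.11.15, scanpy 1.11.5, scipy 1.17.1, leidenalg 0.10.2, scikit-learn 1.9.0, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.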

Results

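Single cells of subcutaneous tumours from mice were profiled by droplet RNA sequencing in 8 libraries, 4 of a group that the labels call C (C1 to C4) and 4 of a group called U (U1 to U4). The series title concerns remodelling of the tumour microenvironment by UCA. The labels spell out neither the group letters nor that abbreviation. The deposited matrices held 81573 cell barcodes and 933769925 unique molecular identifiers (UMIs, counts of single RNA molecules), from 75779540 in U2 to 155494977 in U4. After filtering, 70142 cells remained, between 4767 in U3 and 11980 in C4, with a median of 6700 (C3) to 11905 (U3) UMIs per cell. Nothing in the labels says that the libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical. C1, C2 and U1 were processed with Cell Ranger 5.0.0 and the other 5 libraries with 6.0.2. In the sums of all cells, principal component 1 (47.7% of the variance) separated the versions. It put 5.0.0 at -58.2 to -51.2 and 6.0.2 at 23.9 to 37.9. Values within the 6.0.2 libraries (2 of C, 3 of U) are therefore given beside the pooled ones. The 5.0.0 libraries hold 1 library of U, so they give values and no test of shares that could pass.

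Monocytes and macrophages made up most of the cells in both groups. They were 69.98 ± 4.42% in C and 70.1 ± 12.0% in U of all kept cells (means ± SD over the 4 libraries of a group, here and wherever no n is given), with 73.6% in C and 76.1% in U in 6.0.2, 66.4% and 52.1% in 5.0.0. T and NK cells made up 10.9 ± 3.87% in C and 10.4 ± 6.84% in U (8.14% in C and 7.12% in U in 6.0.2, 13.6% and 20.4% in 5.0.0). Cells with few transcripts of Ptprc, which encodes the leukocyte surface protein CD45, were 11.8 ± 2.38% in C and 13.1 ± 4.28% in U (12.2% and 11.02% in 6.0.2). Their clusters were led by Tm4sf1, Gng11, Rhox5, Dcn and Col3a1, and no cluster earned a tumour-like name (92 cells at another Leiden resolution and 50 without library balancing did), so they are called Ptprc-low cells here. Dendritic cells were 3.01 ± 0.582% in C and 2.58 ± 0.499% in U (3.35% and 2.60% in 6.0.2). Endothelial cells, which line blood vessels, were 1.17 ± 0.821% in C and 0.630 ± 0.351% in U (0.511% and 0.459% in 6.0.2).

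Neutrophils were 0.560 ± 0.601% in C and 0.939 ± 1.12% in U, mast cells or basophils 0.266 ± 0.197% in C and 0.160 ± 0.263% in U and fibroblasts 0.205 ± 0.0623% in C and 0.320 ± 0.249% in U (1.66% and 2.01% at another Leiden resolution). B and plasma cells were 0.0870 ± 0.0499% in C and 0.0903 ± 0.0475% in U and pericytes 0.0910 ± 0.0440% in C and 0.0795 ± 0.0792% in U (order turned at another Leiden resolution and without balancing). Cells of clusters left without a name were 1.98 ± 1.35% in C and 1.56 ± 0.696% in U. In 6.0.2 the shares in C and U were 0.824% and 0.990% for neutrophils, 0.103% and 0.0284% for mast cells or basophils, 0.188% and 0.196% for fibroblasts and 0.0598% and 0.0407% for pericytes, and in the opposite order 0.126% and 0.0782% for B and plasma cells and 0.912% and 1.39% for unnamed clusters. None of the 11 classes differed between the groups beyond the spread between libraries, by a 2-sided exact permutation test over 70 reassignments of the libraries (smallest adjusted p = 0.971, smallest p without adjustment 0.229, the smallest that 4 against 4 can give being 0.0286). edgeR on the cell counts also called 0 of the 11, with 0 at an unadjusted p under 0.05 (smallest adjusted p = 0.993). U1 held 52.1% monocytes and macrophages (95% Wilson interval 51.0 to 53.1%, counting error only), 20.4% T and NK cells and 19.4% Ptprc-low cells.

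**Figure D1:**
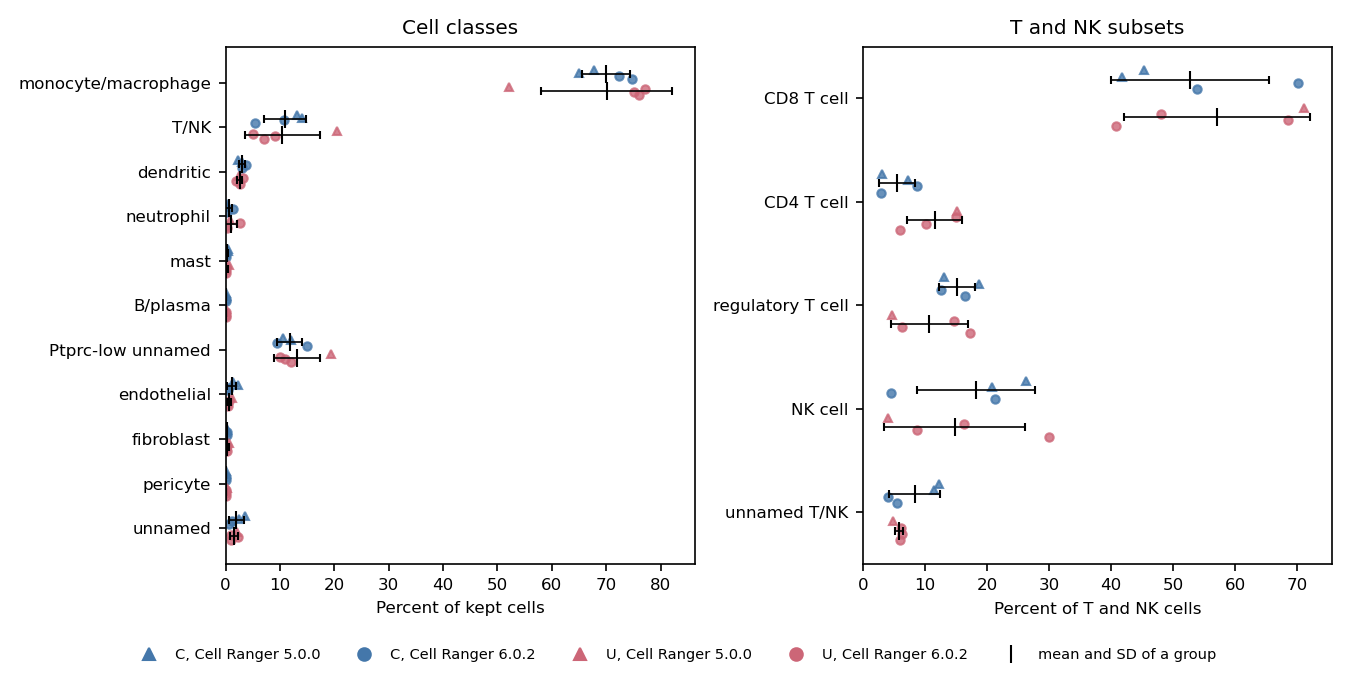
Share of each cell class among all kept cells, and of T and NK cell subsets among T and NK cells (percent), in each library of C and U, with group means and SD. Monocytes and macrophages average 69.98% in C and 70.1% in U, and CD4 T cells 5.49% and 11.6% of T and NK cells.

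Among T and NK cells, CD4 T cells made up 5.49 ± 2.90% in C and 11.6 ± 4.39% in U, with 4 of 4 U libraries above the median of C. They were 5.79% in C and 10.3% in U in 6.0.2, 5.18% and 15.2% in 5.0.0. The difference did not pass the exact permutation test (p = 0.0857, adjusted p = 0.429 over 5 subsets), nor edgeR on the cell counts after adjustment (log2 fold change 1.06, p = 0.0435, adjusted p = 0.218). Without library balancing, 310 of the 643 CD4 T cells were named CD8 T cells, and the share was 1.19 ± 0.618% in C and 5.41 ± 7.85% in U (17.1% in U1, 0.693 to 3.04% in U2 to U4), with 2 of 4 U libraries above the median of C. CD8 T cells, the cytotoxic T cells, were 52.8 ± 12.7% in C and 57.1 ± 15.02% in U. Regulatory T cells, which restrain immune responses, were 15.2 ± 2.90% in C and 10.7 ± 6.19% in U, and NK cells 18.2 ± 9.50% in C and 14.8 ± 11.3% in U. In 6.0.2 CD8 T cells were 62.1% in C and 52.5% in U and NK cells 12.9% and 18.4%, both in the opposite order, and regulatory T cells 14.5% and 12.7%. The log2 ratio of CD8 to regulatory T cells was 1.79 ± 0.54 in C and 2.58 ± 1.31 in U (exact permutation p = 0.343), and 2.10 and 2.14 in 6.0.2. T and NK cells left without a subset name were 8.35 ± 4.15% in C and 5.80 ± 0.598% in U, and in the opposite order 4.80% and 6.09% in 6.0.2. They came from a sub-cluster mostly of doublets led by Cd74, C1qa and Apoe (1.74% and 1.96% of T and NK cells in C and U) and 1 led by Gm26917, Lars2 and Cxcl10 (6.61% and 3.84%).

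Within the mononuclear phagocytes (monocytes, macrophages and dendritic cells), conventional dendritic cells of type 2, which present antigen to CD4 T cells, made up 1.61 ± 0.253% in C and 1.07 ± 0.281% in U, with 4 of 4 U libraries below the median of C. Adjusted over 7 subsets, the exact test likewise could not pass for a subset on its own. The difference missed the threshold (exact permutation p = 0.0571, adjusted p = 0.400, and by edgeR log2 fold change -0.58, p = 0.0382, adjusted p = 0.268). The shares were 1.74% in C and 0.952% in U in 6.0.2, 1.47% and 1.41% in 5.0.0. At another Leiden resolution, where 342 of 429 cells of a sub-cluster unnamed here (led by Ly6c2, Ms4a4c and Cd209a) took this name, the share was 2.18 ± 0.507% in C and 1.78 ± 0.410% in U (adjusted p = 0.914), and 2.54% and 2.15% without balancing. Macrophages were 76.4 ± 5.66% in C and 75.1 ± 8.51% in U and monocytes 19.5 ± 5.13% in C and 21.3 ± 7.99% in U (77.7% and 77.3%, and 17.96% and 19.4%, in 6.0.2). Without balancing, 3324 of the 3670 monocytes of C1, C2 and U1 were named macrophages, and monocytes were 10.97 ± 10.8% in C and 14.5 ± 9.37% in U (69, 144 and 91 cells in C1, C2 and U1). Conventional dendritic cells of type 1 were 0.821 ± 0.138% in C and 0.589 ± 0.2996% in U (0.773% and 0.539% in 6.0.2), dendritic cells that express the migration receptor Ccr7 0.524 ± 0.201% in C and 0.695 ± 0.440% in U (0.370% and 0.616% in 6.0.2). Plasmacytoid dendritic cells were 0.200 ± 0.125% in C and 0.182 ± 0.0730% in U (0.277% and 0.158% in 6.0.2) and dendritic cells without a subset name 0.968 ± 0.364% in C and 1.09 ± 0.220% in U, none past the threshold. The order of the last turned in 6.0.2 (1.20% and 1.03%) and at another Leiden resolution.

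In the sum of all cells of a library, the genes with the smallest p, none past the threshold, were H2-M2 1.79 (1.55), Gm17056 -1.51 (-0.89), Angptl4 -0.72 (-0.58), A430035B10Rik -1.16 (-0.78) and Nts -3.32 (-1.24). Genes are given from here on as log2 fold changes, with those in 6.0.2 in parentheses. H2-M2, a non-classical class I histocompatibility gene (ENSMUSG00000016283, chromosome 17, 37480851 to 37483552 on the minus strand of GRCm38) had 0.634 ± 0.0747 CPM in C and 2.20 ± 0.895 in U, a log2 fold change of 1.79 ± 0.33 (SE). In this sum edgeR called 0 of 15797 genes (402 at an unadjusted p under 0.05) and DESeq2 7 (1 higher, 6 lower). In 6.0.2 edgeR called 0 genes in each sum but that of CD4 T cells, with 34 to 206 at an unadjusted p under 0.05. In 5.0.0, where the 1 library of U is assumed to vary like C, it called 206 to 3459. Gm17056 is annotated as antisense and cannot be told apart from its partner gene unless the counting used strand.

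The value that opens the parentheses after each gene list is the median log2 fold change of its tested members, followed by that in 6.0.2 and the number of members above or below 0. Over the 10 sums, camera with a preset correlation of 0.01 called 83 of 305 pairs of list and sum, 33 higher and 50 lower in U. Camera with an estimated correlation and fry each called 0 (smallest adjusted p = 0.715 and 0.855), so none of the 83 calls holds there. With the Cell Ranger version as a term camera called 61 pairs, 53 among the 83. In 6.0.2 it called 41 of 307, 32 among the 83. Where leaving out 1 library ended a call, the highest adjusted p stands in parentheses, and where it moved a median by over 1.5 times while the call stayed, that median does. No member of any called list passed over all genes tested, and the count passing adjusted over the list alone was 0 except where it is given.

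Besides the stress lists described next, the sum of all cells held 4 lists higher and 7 lower in U. Higher were interferon gamma response (0.23, 0.40 in 6.0.2, 19 of 24 above 0, adjusted p = 0.00377), hypoxia (0.14, 0.18 in 6.0.2, 16 of 20 above 0, adjusted p = 0.0124), glycolysis (0.12, 0.16 in 6.0.2, 15 of 18 above 0, adjusted p = 0.0309) and extracellular matrix (0.36, 0.093 in 6.0.2, 23 of 28 above 0, adjusted p = 0.00163). These all-cell lists had adjusted p = 0.731 to 0.757 with an estimated correlation. Lower were cytotoxicity (-0.19, -0.033 in 6.0.2, 13 of 20 below 0, adjusted p = 0.00205), T cell exhaustion (-0.46, -0.32 in 6.0.2, 13 of 15 below 0, adjusted p = 0.000436), regulatory T cell programme (-0.56, -0.012 in 6.0.2, 15 of 17 below 0, adjusted p = 9.91e-05) and inflammatory myeloid genes (-0.26, 0.053 in 6.0.2, 17 of 22 below 0, adjusted p = 0.00677). These all-cell lists had adjusted p = 0.719 to 0.731 with an estimated correlation. Also lower were chemokines that recruit T cells (-0.39, 0.18 in 6.0.2, 5 of 9 below 0, 2 passing adjusted over the list alone, adjusted p = 0.0428), angiogenesis and tip cell genes (-0.39, 0.14 in 6.0.2, 16 of 19 below 0, adjusted p = 0.000314) and tumour-like epithelial genes (-1.01, -0.22 in 6.0.2, 8 of 9 below 0, adjusted p = 0.00798). These all-cell lists had adjusted p = 0.731 with an estimated correlation. U1 held the most fibroblasts (0.692%) and Ptprc-low cells (19.4%) of the 8 libraries. Endothelial cells were 1.17% of cells in C and 0.630% in U, and regulatory T cells 15.2% and 10.7% of T and NK cells. In all cells the version as a term ended the calls of interferon gamma (adjusted p = 0.102), cytotoxicity (0.101), inflammatory genes (0.485), T cell chemokines (0.276) and angiogenesis (0.0563). Within 6.0.2 interferon gamma, exhaustion, hypoxia and glycolysis also passed. Calls ended for interferon gamma without C4 or U3 (0.605), cytotoxicity without C1 or U2 (0.213) and inflammatory genes without C1 or C2 (0.175). Others ended for T cell chemokines without C1, C2, C3, U1, U2 or U3 (0.159), hypoxia without C3, C4, U1 or U4 (0.441) and glycolysis without C3, C4, U1 or U4 (0.441). Others ended for matrix without C3 or U1 (0.969, the test's direction turned with a median of 0.0074 without U1), angiogenesis without C2 or U3 (0.0846) and epithelial genes without C4, U1 or U4 (0.280). Medians moved for cytotoxicity (-0.29 without C4, -0.34 without U1 and -0.74 without U4), exhaustion (-0.73 without U4) and regulatory programme (-0.36 without C2 and -0.86 without C4). Others moved for inflammatory genes (-0.55 without U1), T cell chemokines (-0.24 without U4) and hypoxia (0.21 without C2 and 0.23 without U2). Others moved for glycolysis (0.22 without U2), angiogenesis (-0.63 without C4, -0.69 without U1 and -0.69 without U4) and epithelial genes (-0.51 without C1, -0.66 without U2 and -3.54 without U3).

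Heat shock genes and immediate early genes, which cells switch on under stress, tissue dissociation included, were lower in U in all 10 sums. Adjusted p by camera was 2.69e-12 to 7.78e-07 for heat shock genes and 1.33e-16 to 0.0229 for immediate early genes, and none of these calls held with an estimated correlation (adjusted p = 0.715 to 0.757). Of heat shock genes, every tested member lay below 0 in each sum, from 11 members in CD4 T cells to 13 in all cells. In macrophages Hspa1a, which encodes an inducible HSP70 chaperone, averaged 1498 ± 1350.0 CPM in C and 253 ± 75.7 in U, a log2 fold change of -2.57 ± 0.64 (SE). Atf3, a transcription factor induced by stress (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039 on the minus strand), averaged 1721 ± 673 CPM in C and 721 ± 118 in U, a log2 fold change of -1.26 ± 0.28 (SE). The medians of the heat shock list ran from -2.02 in CD4 T cells to -0.93 in endothelial cells, and in 6.0.2 from -0.35 in endothelial cells to -0.11 in CD4 T cells (C3 alone in C). Those of the immediate early list ran from -1.06 in Ptprc-low cells to -0.33 in NK cells, and in 6.0.2 from -0.38 in CD8 T cells to -0.13 in NK cells.

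Heat shock genes stood higher in C1 and C2 than in each other library in all 10 sums. In macrophages the heat shock list averaged 8.998 and 8.49 log2 CPM in C1 and C2, 7.14 and 7.18 in C3 and C4, and between 6.66 and 7.10 in U. Adjusted over the list alone, heat shock genes passed for 4 of 13 in all cells, 9 of 13 in macrophages, 7 of 13 in monocytes, 10 of 12 in CD8 T cells, 10 of 11 in CD4 T cells, 11 of 12 in dendritic cells and 6 of 13 in Ptprc-low cells. Immediate early genes did so for 5 of 18 in all cells, 6 of 18 in macrophages, 3 of 18 in CD8 T cells, 8 of 18 in CD4 T cells and 11 of 18 in Ptprc-low cells. With the version as a term both lists kept their calls except immediate early genes in NK cells (adjusted p = 0.0935). In 6.0.2 the call ended for heat shock genes in monocytes, CD4, regulatory T and NK cells (adjusted p = 0.111, 0.848, 0.361 and 0.349). There it also ended for immediate early genes in CD4 T cells and dendritic cells (adjusted p = 0.216 and 0.110). Leaving out 1 library ended the call only for immediate early genes in NK cells, without C2, C3 or U4 (medians -0.17, -0.20 and -0.17, adjusted p up to 0.666). Among calls that stayed it moved a median by over 1.5 times for heat shock genes without C1, to -0.76 in macrophages and -0.55 in endothelial cells. Medians of immediate early genes moved likewise without U1, to -0.26 in monocytes and -0.95 in endothelial cells.

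**Figure D2:**
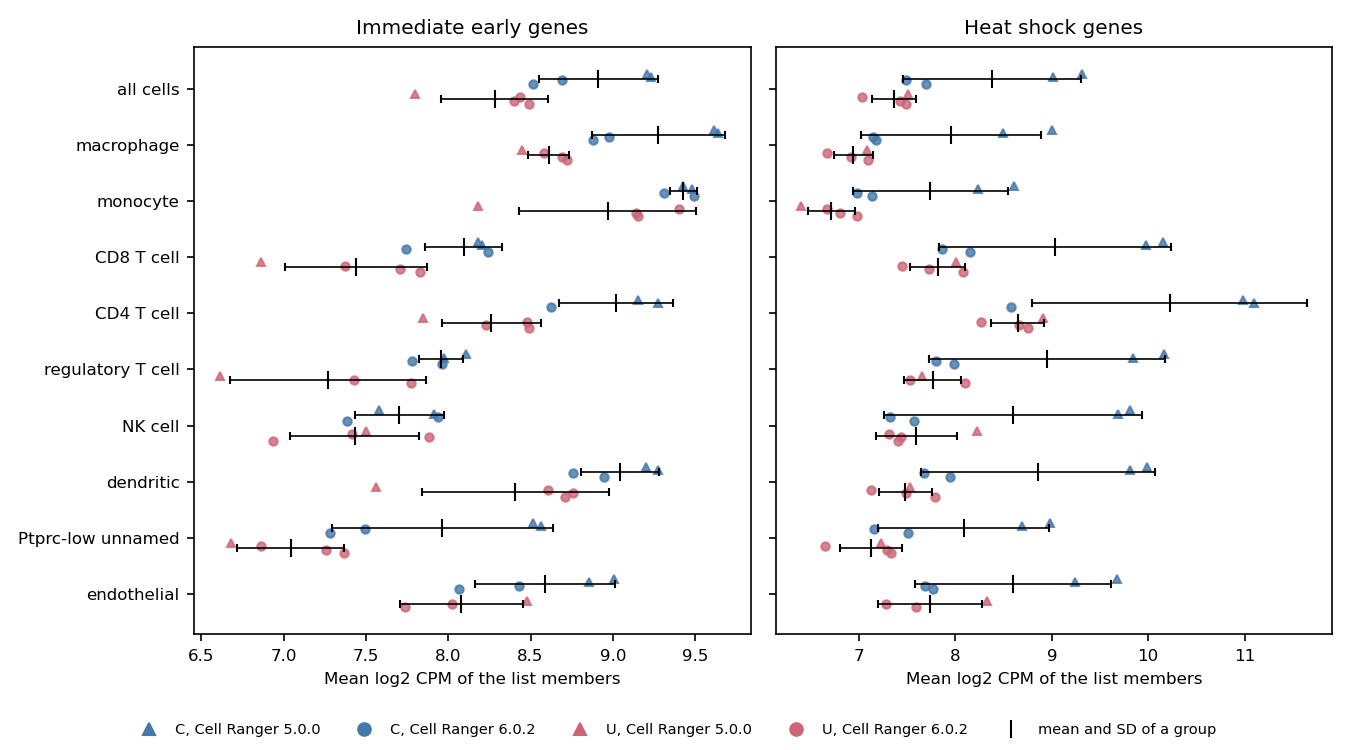
Mean log2 CPM of the heat shock list and the immediate early list per library in the sum of all cells and in each class, with C and U libraries as points and group means marked. C1 and C2 lie highest for heat shock genes, as in CD8 T cells (10.2 and 9.97), where U libraries lie between 7.45 and 8.08.

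In macrophages, hypoxia and glycolysis genes were higher in U, and inflammatory myeloid genes and type I interferon genes were lower. Within the hypoxia list (0.30, 0.33 in 6.0.2, 19 of 20 above 0, adjusted p = 0.00163, adjusted p = 0.731 with an estimated correlation) the members with the smallest p were the adenylate kinase Ak4 0.71 (0.85), Pdk1 0.42 (0.38), which limits entry of pyruvate into mitochondria, and the oxygen sensor Egln1 0.38 (0.26). The glycolysis list (0.18, 0.25 in 6.0.2, 14 of 18 above 0, adjusted p = 0.00287, adjusted p = 0.731 with an estimated correlation) was led by the lactate exporter Slc16a3 0.59 (0.62) and the enzymes Aldoc 0.50 (0.78) and Pfkl 0.31 (0.37). Inflammatory myeloid genes fell as a list (-0.28, -0.033 in 6.0.2, 15 of 21 below 0, 2 passing adjusted over the list alone, adjusted p = 0.00104, adjusted p = 0.748 with an estimated correlation), led by the chemokines Ccl4 -1.92 (-0.72) and Ccl3 -1.92 (-0.78) and by Tnf -1.59 (-0.27). Ccl4 averaged 6703 ± 3946 CPM in C and 1777 ± 525 in U, a log2 fold change of -1.92 ± 0.46 (SE). Type I interferon genes also fell (-0.24, 0.045 in 6.0.2, 18 of 22 below 0, adjusted p = 0.000468, 0.748 with an estimated correlation), among them Ifit1 -1.71 (-0.35), Oasl1 -1.996 (-0.26) and Ifit3b -0.88 (-0.29). Chemokines that recruit T cells were lower (-0.088, 0.090 in 6.0.2, 5 of 9 below 0, 2 passing adjusted over the list alone, adjusted p = 0.0163) and extracellular matrix genes higher (0.46, -0.0070 in 6.0.2, 21 of 24 above 0, adjusted p = 0.00187). These macrophage lists had adjusted p = 0.715 to 0.731 with an estimated correlation. Tm4sf1, which leads Ptprc-low clusters, had a UMI in 7.64% of macrophages. A macrophage cluster led by Ccl4, Ccl3, Cxcl2, Rsad2, Oasl1 and Atf3 held 47.2% of macrophages in C1 and 44.6% in C2 and between 0.921% and 6.68% in the other 6 libraries. Clusters led by Arg1 held most in U1 (40.2%) and U2 (26.7%) and 1 led by Apoe and C1qa in C4 (27.4%).

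Of single genes in macrophages, edgeR called 0 of 13037 genes (580 at an unadjusted p under 0.05) and DESeq2 18 of the 1156 with an adjusted p (0 higher, 18 lower). Macrophage genes with the smallest p were H2-M2 1.86 (1.76), Gm16310 -2.99 (-1.37), Gm17056 -1.14 (-0.93), Atf3 -1.26 (-0.57) and Fam214a -0.61 (-0.56). The fixed panel of myeloid genes gave Cd274 0.27 (0.51), Arg1 0.85 (1.16), Nos2 1.09 (1.34), Mrc1 0.64 (0.50), Spp1 0.23 (0.63), Cxcl9 0.28 (0.18), Cxcl10 -1.18 (0.10), Vegfa 0.0051 (0.27), Il1b -0.16 (-0.49), Il10 -1.06 (-0.032), Tgfb1 0.26 (0.16) and H2-Ab1 -0.25 (-0.48), none past the threshold. In 5.0.0 Il1b, Spp1 and Tgfb1 changed sign. In macrophages the version as a term ended the calls of inflammatory genes (adjusted p = 0.504) and T cell chemokines (0.259). Within 6.0.2 hypoxia and glycolysis also passed. Without balancing the median of T cell chemokines moved to -0.055. Calls ended for type I interferon without C1 or U1 (0.0929), inflammatory genes without C2 or U2 (0.0860) and T cell chemokines without C2 or U2 (0.111). Others ended for hypoxia without C4 or U4 (0.155), glycolysis without C4 or U4 (0.131) and matrix without U1 (0.549). Medians moved for inflammatory genes (-0.13 without C1 and -0.73 without U1), T cell chemokines (-0.19 without C4, -0.20 without U1, -0.24 without U3 and -0.14 without U4) and glycolysis (0.28 without C2).

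In monocytes, genes induced by interferon gamma were higher in U (0.27, 0.34 in 6.0.2, 20 of 23 above 0, adjusted p = 0.00104, 0.731 with an estimated correlation). They included the interferon-induced GTPases Gbp5 0.67 (0.53) and Irgm2 0.62 (0.54). Genes of alternatively activated macrophages rose as a list (0.52, 0.37 in 6.0.2, 17 of 19 above 0, adjusted p = 0.00551), as did extracellular matrix genes (0.44, -0.0028 in 6.0.2, 16 of 18 above 0, adjusted p = 0.00163). These monocyte lists had adjusted p = 0.715 to 0.731 with an estimated correlation. Inflammatory myeloid genes were lower (-0.080, 0.024 in 6.0.2, 11 of 20 below 0, adjusted p = 0.0175, 0.757 with an estimated correlation). A cluster led by Il1b and Cxcl2 held 68.5%, 65.4% and 72.0% of the monocytes of C1, C2 and U1 and between 8.46% and 18.1% elsewhere, where a cluster led by Tgfbi, Lyz2 and Ly6c2 was the largest. For single genes edgeR called 0 of 10729 genes (298 at an unadjusted p under 0.05) and DESeq2 0. Monocyte genes with the smallest p were Gm17056 -1.18 (-1.13), Dtx3 0.86 (0.60), Rab9 -0.75 (-0.42), Tnfrsf14 1.22 (1.17) and Pwwp2b -0.69 (-0.43). The myeloid panel gave Cd274 0.13 (0.45), Arg1 0.34 (0.58), Nos2 0.81 (0.58), Mrc1 0.61 (1.00), Spp1 -0.30 (-0.18), Cxcl9 0.47 (0.58), Cxcl10 -0.17 (0.46), Vegfa -0.25 (0.011), Il1b 0.031 (-0.29), Il10 -1.91 (-0.48), Tgfb1 0.16 (0.0091) and H2-Ab1 -0.10 (-0.037), none past the threshold. In 5.0.0 Tgfb1 changed sign. In monocytes the version as a term ended the call of inflammatory genes (adjusted p = 0.988), and clustering without balancing those of interferon gamma (0.265), inflammatory genes (0.108), alternative activation (0.455) and matrix (0.237). Within 6.0.2 interferon gamma also passed. Calls ended for interferon gamma without C4 or U3 (0.142), inflammatory genes without C1, C2, U2, U3 or U4 (0.415, the median 0.027 without C1) and alternative activation without C3 or U1 (0.249). Others ended for matrix without U1 (0.633). Medians moved for inflammatory genes (-0.18 without C3, -0.21 without C4 and -0.82 without U1) and alternative activation (0.18 without U2).

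In CD8 T cells, exhaustion genes, which T cells express under lasting stimulation, were lower in U and interferon gamma response genes higher. The exhaustion list (-0.53, -0.29 in 6.0.2, 13 of 15 below 0, 1 passing adjusted over the list alone, adjusted p = 1.08e-05, adjusted p = 0.715 with an estimated correlation) was led by Tox -1.23 (-1.05), a transcription factor of exhausted T cells, Nr4a2 -0.93 (-0.58) and Rgs16 -1.35 (-0.70). Tox (ENSMUSG00000041272, chromosome 4, 6686353 to 6991557 on the minus strand) averaged 74.1 ± 15.02 CPM in C and 31.2 ± 13.3 in U, a log2 fold change of -1.23 ± 0.29 (SE), edgeR adjusted p = 0.951. The interferon gamma list (0.37, 0.43 in 6.0.2, 19 of 22 above 0, adjusted p = 0.000138, adjusted p = 0.715 with an estimated correlation) included Gbp2 0.86 (0.51), Igtp 0.96 (0.70) and the chemokine Cxcl10 -1.50 (0.44), which lay lower in U over all libraries and higher in 6.0.2. Type I interferon genes were also higher (0.26, 0.23 in 6.0.2, 16 of 21 above 0, adjusted p = 0.0193, 0.762 with an estimated correlation). Genes of the regulatory T cell programme were lower (-0.41, -0.090 in 6.0.2, 11 of 12 below 0, adjusted p = 0.0163), as were apoptosis and p53 target genes (-0.40, -0.16 in 6.0.2, 12 of 15 below 0, adjusted p = 0.0170). These CD8 lists had adjusted p = 0.715 to 0.731 with an estimated correlation. Heat shock genes with the smallest p here were Dnaja1 -1.46 (-0.50), Hspa1a -2.98 (-0.62) and Hspa1b -2.13 (-0.51).

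Lists of other cell types moved with the group in CD8 T cells. Genes of alternatively activated macrophages rose as a list (0.63, 0.24 in 6.0.2, 7 of 8 above 0, adjusted p = 0.00125), among them Arg1 1.38 (1.00), Msr1 1.14 (0.59) and Pf4 0.69 (0.22), as did myeloid suppressor genes (0.57, 0.48 in 6.0.2, 8 of 8 above 0, adjusted p = 0.00242) and extracellular matrix genes (0.80, 0.067 in 6.0.2, 6 of 6 above 0, adjusted p = 0.0323). These CD8 lists had adjusted p = 0.715 to 0.731 with an estimated correlation. All 7 tested macrophage markers lay above 0 in CD8 T cells, with a median log2 fold change of 0.33, and at 2.11 to 3.49% of their macrophage level. C1qa, a macrophage gene, had a UMI in 47.4% of CD8 T cells (median 4564 UMIs per cell) and 97.8% of macrophages (median 7799). A sub-cluster led by Ccl1, Pdcd1, Lag3 and Ifng, the largest in C1, C2, C4 and U4, held 55.7% of CD8 T cells in C and 24.9% in U (26.0% in C3, 55.3% in U4), and 1 led by Ccl5, Ly6c2, Iglc1 and Gzmk, the largest in C3, U1, U2 and U3, 16.5% and 35.8%. Another led by cell cycle genes held 19.0% and 21.8%, and 1 led by interferon-induced genes such as Ifit3 8.76% and 17.4%. These shares were not tested, since the sub-clusters are defined by genes compared here.

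**Figure D3:**
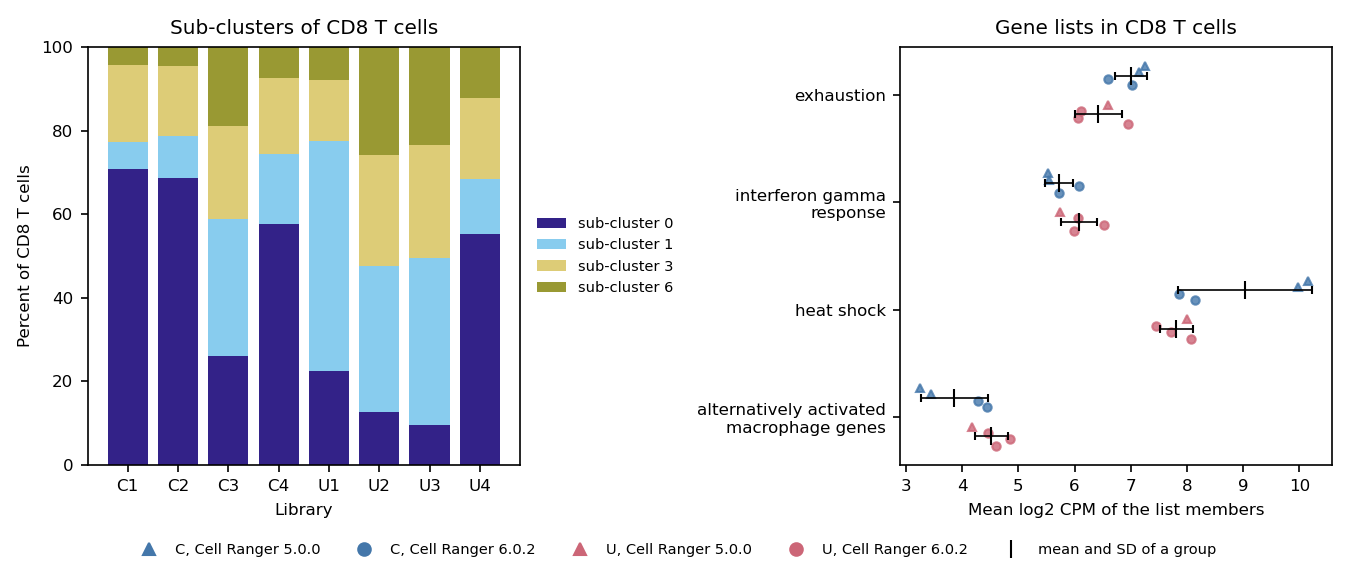
Left, percent of CD8 T cells in each CD8 sub-cluster per library; right, mean log2 CPM of the exhaustion list in CD8 T cells per library, with group means and SD. The list averages 7.01 ± 0.287 log2 CPM in C and 6.42 ± 0.420 in U, and the sub-cluster led by Ccl1 and Pdcd1 holds 70.8% of CD8 T cells in C1 and 9.43% in U3.

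Of single genes in CD8 T cells, edgeR called 0 of 9396 genes (439 at an unadjusted p under 0.05) and DESeq2 11 of the 652 with an adjusted p (1 higher, 10 lower). CD8 genes with the smallest p were Fosb -1.16 (-0.81), Jun -1.24 (-0.59), Gzmm 1.87 (1.56), Tox -1.23 (-1.05) and Gm16310 -1.76 (not tested). The lymphocyte panel gave Ifng -0.89 (-0.16), Gzmb 0.39 (0.51), Prf1 -0.0094 (0.18), Pdcd1 -0.84 (-0.60), Havcr2 -0.43 (-0.061), Lag3 -0.53 (-0.12), Tigit -0.41 (-0.60), Tcf7 0.62 (-0.0096) and Ctla4 -0.58 (-0.29), none past the threshold, and Foxp3 was not tested. In CD8 T cells the version as a term ended the calls of type I interferon (adjusted p = 0.101) and regulatory programme (0.123), and clustering without balancing those of type I interferon (0.135) and regulatory programme (0.0531). Within 6.0.2 interferon gamma, type I interferon and exhaustion also passed. Without the interferon-led sub-cluster the calls of type I interferon (median 0.063, adjusted p = 0.993) and matrix (0.136) ended and the median of interferon gamma moved to 0.24. Calls ended for type I interferon without C2, C4, U2 or U3 (0.284), regulatory programme without C1, U2 or U3 (0.190) and apoptosis without C1 (0.0754). Others ended for matrix without C1, C3 or U1 (0.271). Medians moved for interferon gamma (0.24 without U3), type I interferon (0.42 without C3) and regulatory programme (-0.76 without U4). Others moved for alternative activation (1.08 without C4) and suppressor genes (0.27 without U1).

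In CD4 T cells, glycolysis genes (0.50, 0.10 in 6.0.2, 11 of 12 above 0, adjusted p = 0.000651) and hypoxia genes (0.39, 0.31 in 6.0.2, 6 of 8 above 0, adjusted p = 0.0439) were higher in U. These CD4 lists had adjusted p = 0.715 with an estimated correlation. Heat shock genes with the smallest p here were Dnaja1 -1.84 (-0.18), Hspa8 -1.45 (-0.063) and Dnajb1 -2.35 (-0.71). Gene by gene, edgeR called 0 of 3102 genes (186 at an unadjusted p under 0.05) and DESeq2 22 of the 1535 with an adjusted p (1 higher, 21 lower). CD4 genes with the smallest p were Ifih1 -1.96 (-0.65), Fos -1.52 (-0.67), Dnaja1 -1.84 (-0.18), Mrps6 -1.63 (-0.75) and Ly6c2 1.65 (1.28). The lymphocyte panel gave Ifng -0.24 (0.13), Gzmb 1.998 (2.05), Pdcd1 -0.71 (-0.11), Tcf7 0.45 (0.078) and Ctla4 0.073 (0.50), none past the threshold, and Prf1, Havcr2, Lag3, Tigit, Tox and Foxp3 were not tested. Without C3, edgeR called 81 genes, and without a low-count filter 41. In 6.0.2 C was C3 alone, assumed to vary like U, and edgeR called 4 genes, named after their values were seen, which were Csf2 and Areg (lower in U) and Ifitm1 and Zfp871 (higher). With the version as a term it called 1, Csf2, which encodes the growth factor GM-CSF (-3.19, adjusted p = 0.00218). In 5.0.0 Ctla4 changed sign. In CD4 T cells the version as a term ended the call of hypoxia (adjusted p = 0.0575). None of these lists passed within 6.0.2. Without balancing too few CD4 T cells were left to test. Calls ended for hypoxia without C3 or U2 (0.0702). Medians moved for hypoxia (0.58 without U1).

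In regulatory T cells, type I interferon genes fell as a list (-0.77, -0.17 in 6.0.2, 18 of 19 below 0, adjusted p = 1.78e-07, adjusted p = 0.715 with an estimated correlation), led by Ifit3b -2.53 (not tested), Ifit2 -2.92 (not tested) and Ifit3 -2.02 (-1.20). Glycolysis genes rose (0.24, 0.18 in 6.0.2, 14 of 15 above 0, adjusted p = 0.000442), led by the phosphofructokinase Pfkp 0.57 (0.59) and the glucose transporters Slc2a3 0.65 (0.79) and Slc2a1 0.55 (0.28), as did hypoxia genes (0.25, 0.20 in 6.0.2, 13 of 15 above 0, 1 passing adjusted over the list alone, adjusted p = 0.00104). These regulatory T cell lists had adjusted p = 0.715 with an estimated correlation. Lower in U were inflammatory myeloid genes (-0.59, -0.24 in 6.0.2, 10 of 11 below 0, adjusted p = 0.00396), chemokines that recruit T cells (-1.07, -0.64 in 6.0.2, 4 of 6 below 0, adjusted p = 0.0227) and apoptosis and p53 target genes (-0.29, -0.23 in 6.0.2, 9 of 11 below 0, adjusted p = 0.0368). These regulatory T cell lists had adjusted p = 0.715 to 0.731 with an estimated correlation. C1qa had a UMI in 47.0% of regulatory T cells (median 3335 UMIs). Gene by gene, edgeR called 0 of 6312 genes (271 at an unadjusted p under 0.05) and DESeq2 0. Regulatory T cell genes with the smallest p were Dgat2 -2.12 (not tested), Cdca5 -1.75 (-2.06), Ero1l 1.06 (1.07), Xlr4c 1.24 (1.10) and Ifrd1 -1.27 (-0.53). The lymphocyte panel gave Ifng -1.16 (-0.35), Gzmb 0.56 (0.58), Prf1 1.19 (0.85), Pdcd1 -0.052 (-0.27), Havcr2 -0.44 (-0.27), Lag3 0.28 (0.63), Tigit -0.18 (-0.081), Tox 0.15 (0.32), Foxp3 0.10 (0.28) and Ctla4 0.14 (0.26), none past the threshold, and Tcf7 was not tested. In 5.0.0 Ctla4, Pdcd1 and Lag3 changed sign. With the version as a term edgeR called 2 genes, Mt1, a metallothionein (1.18, adjusted p = 0.00547), and Ccr7 (-1.40, adjusted p = 0.0227). Without C4 it called 1, Ifit2 (-3.27, adjusted p = 0.0234), all named after their values were seen, and without a low-count filter 19. U3 did not enter this class, with 27 cells. In regulatory T cells the version as a term ended the call of T cell chemokines (adjusted p = 0.0656), and clustering without balancing that of apoptosis (0.0771). Within 6.0.2 T cell chemokines also passed. Calls ended for inflammatory genes without U2 (0.211), T cell chemokines without U2 (0.303) and apoptosis without C1, C3, U2 or U4 (0.186). Medians moved for type I interferon (-0.51 without C1 and -0.43 without U1), inflammatory genes (-0.38 without C2) and hypoxia (0.38 without C1). Others moved for glycolysis (0.37 without U2).

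In NK cells, Cd3e, a subunit of the T cell receptor complex that NK cells do not carry at their surface, lay closest to the threshold (ENSMUSG00000032093, chromosome 9, 44998740 to 45009627 on the minus strand). It averaged 1.39 ± 1.58 CPM in C and 18.3 ± 3.40 in U, a log2 fold change of 3.23 ± 0.49 (SE), with edgeR adjusted p = 0.0815 and DESeq2 adjusted p = 0.000838. It was higher in 4 of 4 U libraries than the median of C (16.5 to 23.4 CPM in U, 0 to 3.66 in C) and was not tested in 6.0.2, where C3 had 0 CPM. In CD8 T cells Cd3e stood at 415 CPM, and a UMI of it was seen in 2.11% of NK cells (median 8029 UMIs per cell) and 0.541% of macrophages (median 7799). Cd3g, named after its value was seen, was the 1 gene called with the version as a term (1.996, adjusted p = 0.00615). Gene by gene, edgeR called 0 of 6160 genes (245 at an unadjusted p under 0.05) and DESeq2 1, Cd3e, and without a low-count filter edgeR called 41. The other genes with the smallest p were Cd3d 1.67 (1.68), 5430416N02Rik -1.37 (-0.76), Pdgfa -1.51 (-0.83) and Mob4 -0.99 (-0.63). The lymphocyte panel gave Ifng -1.10 (-0.41), Gzmb -0.012 (-0.21), Prf1 0.33 (0.085), Pdcd1 -0.22 (-0.12), Havcr2 1.14 (0.89), Lag3 -0.57 (-0.38), Tcf7 -0.10 (-0.034) and Ctla4 -0.031 (-0.18), none past the threshold, and Tigit, Tox and Foxp3 were not tested. In 5.0.0 Ctla4, Pdcd1 and Tcf7 changed sign.

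As lists in NK cells, MHC class II genes (0.45, -0.14 in 6.0.2, 7 of 7 above 0, adjusted p = 0.0352) and genes of alternatively activated macrophages (1.04, not tested in 6.0.2, 5 of 6 above 0, adjusted p = 0.0368), both of them genes of myeloid cells, were higher in U. These NK cell lists had adjusted p = 0.715 to 0.762 with an estimated correlation. Type I interferon genes (-0.24, 0.012 in 6.0.2, 11 of 16 below 0, adjusted p = 0.0286) and genes of the unfolded protein response (-0.19, 0.00067 in 6.0.2, 12 of 16 below 0, adjusted p = 0.0394) were lower. These NK cell lists had adjusted p = 0.731 to 0.752 with an estimated correlation. C1qa had a UMI in 53.4% of NK cells. In NK cells the version as a term ended the calls of type I interferon (adjusted p = 0.0889), MHC class II (0.213), alternative activation (0.199) and unfolded protein response (0.129), and clustering without balancing that of alternative activation (0.0531). None of these lists passed within 6.0.2. Calls ended for type I interferon without C1, C2 or U4 (0.421), MHC class II without C1, C2, U1, U3 or U4 (0.252) and alternative activation without U3 (0.129). Others ended for unfolded protein response without C1, C2, U1 or U4 (0.369). Medians moved for type I interferon (-0.43 without U1 and -0.37 without U3), MHC class II (0.75 without C4) and alternative activation (0.68 without U2). Others moved for unfolded protein response (-0.11 without U2).

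In dendritic cells, genes of DNA synthesis were lower in U (-0.34, -0.31 in 6.0.2, 24 of 24 below 0, adjusted p = 7.06e-08). Those of G2 and mitosis were too (-0.36, -0.34 in 6.0.2, 24 of 24 below 0, adjusted p = 6.20e-08). Gins2 -0.60 (-0.70), Uhrf1 -0.41 (-0.41) and Mcm4 -0.48 (-0.45), which act at replication forks, and Kif11 -0.83 (-0.51), Mki67 -1.31 (-0.37) and Tpx2 -0.68 (-0.54) led them. These dendritic lists had adjusted p = 0.731 with an estimated correlation. Mki67, a marker of cycling cells, averaged 154 ± 102 CPM in C and 61.8 ± 24.96 in U, a log2 fold change of -1.31 ± 0.51 (SE). Sub-clusters led by cell cycle genes held 17.9% of their cells in C (15.7 to 21.4%) and 11.6% in U. U1 to U4 held 8.23, 4.73, 16.9 and 16.5%. Cells that express Ccr7 were 16.7% and 26.8% (9.02% in C4 to 45.9% in U2), neither tested. Type I interferon genes (-0.29, 0.071 in 6.0.2, 17 of 22 below 0, adjusted p = 0.00502), inflammatory myeloid genes (-0.22, 0.0083 in 6.0.2, 15 of 17 below 0, 1 passing adjusted over the list alone, adjusted p = 0.0231), genes of the unfolded protein response (-0.26, -0.10 in 6.0.2, 13 of 16 below 0, adjusted p = 0.00798) and cytotoxicity genes, which are genes of T and NK cells (-1.06, -0.25 in 6.0.2, 3 of 5 below 0, 2 passing adjusted over the list alone, adjusted p = 0.0352), were also lower. These dendritic lists had adjusted p = 0.715 to 0.757 with an estimated correlation. Higher in U were MHC class I genes (0.13, 0.16 in 6.0.2, 15 of 20 above 0, adjusted p = 0.0436) and genes of alternatively activated macrophages (0.45, 0.27 in 6.0.2, 9 of 13 above 0, adjusted p = 0.0142). These dendritic lists had adjusted p = 0.715 to 0.752 with an estimated correlation. C1qa had a UMI in 62.4% of dendritic cells (median 8588 UMIs) and Cd3e in 0.881%. Gene by gene, edgeR called 0 of 8640 genes (234 at an unadjusted p under 0.05) and DESeq2 0. Dendritic genes with the smallest p were Txndc16 -1.32 (-1.03), Vezt 1.61 (1.63), Zfp810 1.22 (1.62), Fmnl3 -1.38 (-1.11) and Ccl3 -1.31 (-0.51). In dendritic cells the version as a term ended the calls of cytotoxicity (adjusted p = 0.276), inflammatory genes (0.775) and unfolded protein response (0.0732), and clustering without balancing that of MHC class I (0.133). Within 6.0.2 S phase and G2 and M phase also passed. Without balancing the medians of type I interferon and inflammatory genes moved to -0.17 and -0.37. Calls ended for type I interferon without C1, U1 or U4 (0.242), MHC class I without C2, C3, C4, U1, U2 or U3 (0.349) and cytotoxicity without C1, C2, U1, U2, U3 or U4 (0.422). Others ended for inflammatory genes without C1, C2, U2 or U4 (0.507), alternative activation without C1 (0.206) and unfolded protein response without C2 (0.0669). Medians moved for MHC class I (0.21 without U4), inflammatory genes (-0.47 without C3, -0.43 without C4 and -0.75 without U1) and alternative activation (0.26 without U2 and 0.69 without U3). Others moved for S phase (-0.16 without U2), G2 and M phase (-0.14 without U2 and -0.62 without U4) and unfolded protein response (-0.14 without U2 and -0.39 without U3).

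In Ptprc-low cells, interferon gamma response genes were higher in U (0.34, 0.63 in 6.0.2, 21 of 24 above 0, adjusted p = 2.23e-05, 0.731 with an estimated correlation), among them the chemokine Cxcl9 0.82 (0.77), the peptide transporter Tap1 0.33 (0.50) and Wars 0.49 (0.58). Type I interferon genes (0.26, 0.46 in 6.0.2, 19 of 22 above 0, adjusted p = 0.00313) and MHC class I genes (0.15, 0.19 in 6.0.2, 17 of 20 above 0, adjusted p = 0.0196) rose with them. These Ptprc-low lists had adjusted p = 0.731 to 0.762 with an estimated correlation. Extracellular matrix genes were higher (0.26, 0.16 in 6.0.2, 24 of 27 above 0, adjusted p = 0.000749, 0.715 with an estimated correlation), with collagens Col1a1 0.78 (1.00) and Col1a2 0.94 (0.61) above 0 and Thbs1 -1.53 (-0.17) below. Col1a2 was at 1.35 CPM in C2 (next in C 2.45), and free RNA of fibroblasts was not tested. Myeloid lists were higher too, namely genes of alternatively activated macrophages (0.60, 0.32 in 6.0.2, 14 of 16 above 0, adjusted p = 0.00255), myeloid suppressor genes (0.29, 0.041 in 6.0.2, 12 of 15 above 0, adjusted p = 0.0368) and lipid-associated macrophage genes (0.17, 0.15 in 6.0.2, 15 of 18 above 0, adjusted p = 0.0428), while cholesterol synthesis genes were lower (-0.14, -0.061 in 6.0.2, 17 of 22 below 0, adjusted p = 0.0406). These Ptprc-low lists had adjusted p = 0.715 to 0.825 with an estimated correlation. C1qa had a UMI in 80.5% of these cells, at 122 CPM against 7542 in macrophages.

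Of single genes in Ptprc-low cells, edgeR called 0 of 13228 genes (286 at an unadjusted p under 0.05) and DESeq2 1, Gm17056. Ptprc-low genes with the smallest p were Gm17056 -2.35 (-0.99), Igfbp4 0.98 (0.97), Casc1 -1.95 (-0.94), 4933408J17Rik -1.63 (-1.36) and Gadd45g -1.20 (-0.43). The panel fixed for tumour-like cells gave B2m 0.12 (0.22), H2-K1 0.13 (0.17), H2-D1 0.16 (0.19), Cd274 0.38 (0.66), Mki67 -0.15 (0.061) and Vegfa -0.12 (0.076), none past the threshold. In 5.0.0 B2m, Cxcl9, Mki67, H2-K1, Tap1, H2-D1 and Cd274 changed sign. In Ptprc-low cells the version as a term ended the calls of type I interferon (adjusted p = 0.105), MHC class I (0.135), alternative activation (0.106), suppressor genes (0.219), lipid-associated genes (0.474) and cholesterol synthesis (0.961), and clustering without balancing those of suppressor genes (0.0531) and cholesterol synthesis (0.0531). Within 6.0.2 interferon gamma, type I interferon and MHC class I also passed. Calls ended for interferon gamma without C4 or U3 (0.0893), type I interferon without C4, U2, U3 or U4 (0.304) and MHC class I without C3, C4, U3 or U4 (0.488). Others ended for alternative activation without C2 or U4 (0.109), suppressor genes without C1, C2, C3, C4, U2, U3 or U4 (0.242) and lipid-associated genes without C1, C2, C3, U3 or U4 (0.476). Others ended for cholesterol synthesis without C1, C2, C4, U2 or U4 (0.400, the test's direction turned with a median of 0.053 without U2) and matrix without U1 (0.171). Medians moved for interferon gamma (0.22 without U2), type I interferon (0.41 without U1) and alternative activation (0.36 without C1 and 0.38 without U2). Others moved for lipid-associated genes (0.31 without C4 and 0.26 without U1) and cholesterol synthesis (-0.31 without C3 and -0.32 without U1).

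In endothelial cells, genes of G2 and mitosis were higher in U (0.23, 0.60 in 6.0.2, 21 of 23 above 0, adjusted p = 9.51e-07), led by Kif11 1.11 (1.94), Bub1 0.75 (1.09) and Top2a 0.76 (1.32), while S phase genes were lower (-0.26, -0.27 in 6.0.2, 13 of 16 below 0, adjusted p = 0.0368). These endothelial lists had adjusted p = 0.731 to 0.762 with an estimated correlation. Hypoxia genes (0.34, 0.10 in 6.0.2, 12 of 17 above 0, adjusted p = 0.0163) and extracellular matrix genes (0.21, 0.023 in 6.0.2, 12 of 13 above 0, adjusted p = 0.00741) were higher, and type I interferon genes (-0.26, 0.21 in 6.0.2, 19 of 22 below 0, adjusted p = 0.0360) and inflammatory myeloid genes (-0.39, -0.84 in 6.0.2, 6 of 11 below 0, 2 passing adjusted over the list alone, adjusted p = 0.0368) lower. These endothelial lists had adjusted p = 0.715 to 0.778 with an estimated correlation. C1qa had a UMI in 54.4% of endothelial cells (median 8408 UMIs). Gene by gene, edgeR called 0 of 6789 genes (140 at an unadjusted p under 0.05) and DESeq2 0. Endothelial genes with the smallest p were Mt2 1.16 (0.64), Mt1 1.22 (0.70), Lrrc8b 1.26 (not tested), Jun -1.09 (-0.58) and Ccl3 -2.11 (-1.60). U3 did not enter this class, with 17 cells. In endothelial cells the version as a term ended the calls of type I interferon (adjusted p = 0.0864), inflammatory genes (0.474), hypoxia (0.0575) and S phase (0.217), and clustering without balancing that of S phase (0.0615). Within 6.0.2 hypoxia and G2 and M phase also passed. Calls ended for type I interferon without C1, U1 or U4 (0.978), inflammatory genes without C1, C2, U2 or U4 (0.149) and hypoxia without C2, U2 or U4 (0.441). Others ended for S phase without C2, C4, U2 or U4 (0.437), G2 and M phase without C3 (0.0632) and matrix without C2 or U1 (0.286). Medians moved for type I interferon (-0.54 without U2), inflammatory genes (-0.67 without C3, -0.014 without C4 and -1.35 without U1) and S phase (-0.42 without C3 and -0.71 without U1). Others moved for G2 and M phase (0.40 without C2, 0.42 without U1 and 0.067 without U4) and matrix (0.39 without C1, 0.98 without C3, 1.29 without U2 and 1.38 without U4).

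For 13 lists camera called no sum. Their smallest adjusted p, with the number of sums tested in parentheses, was 0.105 for naive and memory T cell (9), 0.177 for chemokines that recruit neutrophils and monocytes (9), 0.317 for immune checkpoint ligands and inhibitory factors (10), 0.143 for oxidative phosphorylation (10) and 0.306 for oxidative stress response (NRF2 targets) (9). It was 0.105 for ferroptosis-related genes (10), 0.563 for aryl hydrocarbon receptor targets (2), 0.0885 for TGF-beta response and myofibroblast genes (6) and 0.131 for epithelial to mesenchymal transition (10). It was also 0.130 for endothelial adhesion molecules (6), 0.435 for histidine and urea cycle metabolism (7), 0.149 for muscle genes (neighbouring tissue) (2) and 0.885 for skin epithelium genes (neighbouring tissue) (1). Haemoglobin genes had too few members tested in every sum.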

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

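Tests with the Cell Ranger version, of handling, of free RNA and of other splits for the stress and exhaustion lists were chosen only after the result was seen. The values that follow are those in which 1 library lay far from the other 3 of its group, by its gap to the nearest one divided by the group's range, which stands last in each bracket. This held for 28 of 503 groups of 4 (5.57%), where chance gives about 1 in 20, and groups of 3 were not tested. U1 was the library apart in 11, C3 in 5, C2 in 4, U3 and U4 in 3 each, C4 and U2 in 1 each and C1 in 0.

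Among classes, as percent of kept cells, these were monocytes and macrophages of U1 (52.1% against 75.02%, 0.913), neutrophils of C3 (1.46% against 0.354%, 0.872), mast cells or basophils of U1 (0.554% against 0.0502%, 0.933) and fibroblasts of U1 (0.692% against 0.212%, 0.915). In myeloid cells, in CPM, they were Fam214a in macrophages of C3 (10.1 against 11.03, 0.851), Tgfb1 in macrophages of U1 (37.9 against 152, 0.837) and Ccl4 in macrophages of U1 (990.5 against 2019, 0.960). Likewise apart were Slc16a3 in macrophages of C2 (76.6 against 60.1, 0.831), Nos2 in monocytes of U1 (152 against 37.5, 0.899) and Vegfa in monocytes of U1 (340.2 against 214, 0.870). In CD8 T cells, in CPM, they were Lag3 of U4 (288 against 99.1, 0.916), Tcf7 of C3 (35.2 against 12.7, 0.901) and Tcf7 of U4 (7.69 against 31.7, 0.841). Also in CD8 T cells they were Nr4a2 of U4 (401 against 203, 0.962), Arg1 of C3 (16.5 against 6.33, 0.953) and Pf4 of C4 (26.0 against 10.7, 0.934). Other genes, in CPM, were Ifng in CD4 T cells of U3 (1250.2 against 289, 0.948), Tox in regulatory T cells of C2 (62.9 against 35.1, 0.852) and Cd3e in NK cells of U3 (23.4 against 16.7, 0.973). Further genes were Ifng in NK cells of U3 (334 against 113, 0.954), B2m in Ptprc-low cells of U1 (1998 against 2480.3, 0.835) and Col1a2 in Ptprc-low cells of C2 (1.35 against 2.45, 0.869). Among lists, in mean log2 CPM, these were immediate early genes in all cells of U1 (7.80 against 8.40, 0.870), immediate early genes in CD8 T cells of C3 (7.74 against 8.18, 0.878) and hypoxia in regulatory T cells of C2 (6.14 against 6.43, 0.956). Other lists were heat shock genes in NK cells of U1 (8.23 against 7.44, 0.867), immediate early genes in dendritic cells of U1 (7.56 against 8.61, 0.872) and heat shock genes in Ptprc-low cells of U2 (6.64 against 7.22, 0.841).

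The split by group called 0 genes by edgeR in each of the 10 sums (140 to 580 at an unadjusted p under 0.05, 0 to 22 by DESeq2, over 652 to 15768 genes). Any split gives at least 0, so 35 of 35 splits giving as many says nothing about chance. The highest counts of other splits, with C1, C2, U1 and U2 on 1 side, were 2439 in all cells, 1309 in macrophages, 514 in monocytes, 314 in CD8 T cells, 996 in dendritic cells and 4006 in Ptprc-low cells. In sums of 7 libraries the split by Cell Ranger version, with C1, C2 and U1 on 1 side, gave the most, 343 in CD4 T cells, 704 in regulatory T cells and 533 in endothelial cells. For NK cells it was 312 with C1, C2, C3 and U1 on 1 side. All these sides hold the 5.0.0 libraries, which points to a structure of the samples along the version, and within 6.0.2 edgeR called 0 genes in every sum but CD4 T cells (4, with C3 alone in C). All 35 splits gave list calls, 25 to 94 (C1, C2, C3 and U4 on 1 side), 5 giving at least the real 83. Chance cannot be excluded, and 6.0.2 gave 41.

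The 3 patterns weighed here were chosen after the list calls, their alternatives and some of their ranks among splits had been seen. The first is that immediate early and heat shock genes were lower in U in all 10 sums. Against the Cell Ranger version as the whole cause, 19 of 20 pairs of list and sum kept their camera call with the version as a term and 14 within 6.0.2, though none of the 20 held with an estimated correlation (adjusted p = 0.715 to 0.757). Handling or dissociation of C1 and C2 stays open. The median of the 20 pairs was -0.22 in 6.0.2 (also without U1) and -0.96 over all libraries. Splits with C1 and C2 together put 6 to 20 pairs past the threshold, others 0 to 6, so the count follows these 2. The group may contribute too. Chance cannot be excluded, as 2 of 35 splits gave all 20 (the other with C1, C2, C3 and U3 on 1 side).

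The exhaustion list was lower in CD8 T cells of U. With the version as a term it kept its camera call (adjusted p = 5.81e-05, 2.39e-07 to 0.715 over camera's alternatives, median -0.43; -0.29 and adjusted p = 0.00100 within 6.0.2), which argues against the version as the whole cause. A mix of sub-clusters stays open. With each sub-cluster weighted alike whatever its size, the mean difference within the 4 sub-clusters was 64.8% of the pooled -0.48 log2 CPM. That lies between the bounds of 25% and 75% (both differences without TMM scaling, with which the pooled one was -0.58). Within them it was -0.0042 in the sub-cluster led by Ccl1 and Pdcd1, -0.19 in that led by Ccl5, -0.44 in the cycling one and -0.61 in the interferon-led one. The group may also contribute, but chance cannot be excluded, as 2 of 35 splits gave as small a p (real 8.51e-07, the smallest other 1.79e-08 with C1, C2, C4 and U4 on 1 side).

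Genes of alternatively activated macrophages were higher in CD8 T cells of U. The camera call was kept with the version as a term (adjusted p = 0.00407, 3.48e-06 to 0.715 over camera's alternatives, median 0.58), though not within 6.0.2 (0.24, adjusted p = 0.153). The version as the whole cause therefore stays open. Free RNA of macrophages in the droplets is a candidate explanation, since 7 of the 8 tested members lay under 5% of their macrophage level and the 7 tested macrophage markers had a median log2 fold change of 0.327 in CD8 T cells, just past the bound of 0.3. The exception is Tgfb1, which CD8 T cells express at 108% of the macrophage level. A biological difference between the groups was not tested apart from it.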

How the results depend on the processing

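Settings with the Cell Ranger version, without library balancing and without the interferon-led CD8 sub-cluster were tests chosen after seeing the data. The others were planned. Of 24 differences in share, 169 named genes and 83 list calls, 200, 1910 and 377 values under these settings kept their direction and side of the threshold, leaving out 1 library aside. 259 list values kept the direction of camera's test and lost the call, 83 of them with an estimated correlation and 83 with fry, and 137 gene values gained a call, 90 of them in the 5.0.0 libraries. No share gained a call. Settings that left a class with too few libraries, or a gene or list untested, gave no value. A share or gene that turned changed sign. A list that turned changed the direction of camera's test and is given with its median. Where a value turned or a count moved, the cause was not tested.

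Shares are given in percentage points, U minus C, and genes as log2 fold changes. The 5.0.0 libraries hold 1 library of U, assumed to vary like C, and there edgeR called 3459 genes in all cells, 2231 in macrophages, 1682 in monocytes, 1282 in CD8, 206 in CD4, 258 in regulatory T, 661 in NK, 726 in dendritic, 1364 in Ptprc-low and 280 in endothelial cells. Shares that turned there were monocytes and macrophages -14.3, T and NK 6.78, mast 0.125, pericytes 0.0738 and plasmacytoid dendritic 0.130. Genes that turned in 5.0.0 were Il1b 0.64, Spp1 -0.24 and Tgfb1 -0.97 in macrophages, Tgfb1 -0.94 in monocytes, Ctla4 -0.28 in CD4 T cells and Ctla4 -0.055 and Pdcd1 0.22 in regulatory T cells. Also turned there were Lag3 -0.85 in regulatory T cells, Ctla4 0.58, Pdcd1 0.49 and Tcf7 0.76 in NK cells and B2m -0.19, Cxcl9 -0.0088 and Mki67 0.20 in Ptprc-low cells. Further genes were H2-K1 -0.19, Tap1 -0.048, H2-D1 -0.27 and Cd274 -0.25 in Ptprc-low cells. In 6.0.2 edgeR called 4 genes in CD4 cells (C3 alone in C), camera called 41 pairs, and shares that turned were B and plasma -0.0474, Ptprc-low -1.20, unnamed clusters 0.473, CD8 -9.59, NK 5.48, unnamed T and NK 1.29 and unnamed dendritic -0.174. Lists that turned in 6.0.2, with their medians, were inflammatory genes 0.053 and angiogenesis 0.14 in all cells, type I interferon 0.045 in macrophages, inflammatory genes 0.024 in monocytes and MHC class II -0.14 in NK cells. Other such lists were type I interferon 0.071 and inflammatory genes 0.0083 in dendritic cells and type I interferon 0.21 and matrix 0.023 in endothelial cells. The medians of 6 lists changed sign in 6.0.2 while the test kept its direction, namely T cell chemokines 0.18 in all cells, T cell chemokines 0.090 and matrix -0.0070 in macrophages, matrix -0.0028 in monocytes and type I interferon 0.012 and unfolded protein response 0.00067 in NK cells. Genes that turned in 6.0.2 were Cxcl10 0.10 in macrophages, Il1b -0.29, Cxcl10 0.46 and Vegfa 0.011 in monocytes and Cxcl10 0.44 and Prf1 0.18 in CD8 T cells. Other such genes were Tcf7 -0.0096 in CD8 T cells, Ifng 0.13 in CD4 T cells and Mki67 0.061 and Vegfa 0.076 in Ptprc-low cells. With the version as a term edgeR called 1 genes in CD4, 2 in regulatory T and 1 in NK cells, and cholesterol synthesis 0.017 in Ptprc-low cells turned, as did the sign of the median, not the test, of T cell chemokines 0.030 in all cells. Genes that turned with that term were Tgfb1 -0.23 in macrophages, Cxcl10 0.034 and Tgfb1 -0.31 in monocytes, Prf1 0.029 in CD8 T cells, Ctla4 0.19, Pdcd1 0.14 and Tcf7 0.43 in NK cells and Mki67 0.12 in Ptprc-low cells. Permuted within versions, the shares that turned were monocytes and macrophages -3.49, T and NK 1.77, B and plasma -0.00244 and pericytes 0.0140.

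DESeq2 called 7 genes in all cells, 18 of 1156 in macrophages, 11 of 652 in CD8, 22 of 1535 in CD4, 1 in NK and 1 in Ptprc-low cells, and Vegfa -0.0075 in macrophages and Tcf7 0.012 in NK cells turned with it. Without a low-count filter edgeR called 41 genes in CD4, 19 in regulatory T and 41 in NK cells. With size factors of DESeq2 Vegfa -0.0074 in macrophages turned. The stricter cell filter turned monocytes and macrophages -0.169 and Vegfa -0.00031 in macrophages. Without doublet removal monocytes and macrophages -0.150 and Ctla4 0.022 and Gzmb 0.010 in NK cells turned. Another Leiden resolution turned pericytes 0.0128 and unnamed dendritic -0.0103, and Vegfa -0.013 in macrophages, Ctla4 -0.033 in CD4 T cells and Pdcd1 0.0058 in regulatory T cells. Clustering without balancing turned pericytes 0.0128 and Vegfa -0.058 in macrophages and Il1b -0.10, Cxcl10 0.025, Arg1 -0.035 and Nos2 -0.10 in monocytes, with 55 list calls among 252 pairs and 12 of the 83 calls ended. CD8 T cells without the interferon-led sub-cluster turned Prf1 0.056 in CD8 T cells and ended 2 list calls. Camera with an estimated correlation called 0 pairs and fry 0.

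The replicate numbers did not pair the samples. Deviations of C1 and U1 correlated at 0.470, of C2 and U2 at -0.129, of C3 and U3 at 0.253 and of C4 and U4 at 0.476 across genes, and U1 correlated best with C2 (0.581). With the replicate number as a block edgeR called 12 genes in CD4 cells and camera 76 pairs, 74 of them among the 83. Under the block Il1b -0.23 in monocytes, Ctla4 -0.056 in CD4 T cells, Pdcd1 0.15, Tigit 0.10 and Foxp3 -0.028 in regulatory T cells and Ctla4 0.055 and Tcf7 0.084 in NK cells turned. No share could pass there (exact p at least 0.125).

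Leaving out each library in turn gave 0 to 81 called genes in CD4 cells and 0 to 1 called genes in regulatory T cells, as many as with all libraries in every other sum, and 60 to 87 list calls. Shares that turned without at least 1 library ranged over B and plasma -0.0130 to 0.0265, CD8 -0.296 to 10.2, NK -8.53 to 0.127, Ptprc-low -0.744 to 2.42, T and NK -3.76 to 1.34, fibroblasts -0.00889 to 0.166 and macrophages -4.67 to 1.24. Other shares ranged over monocytes and macrophages -2.27 to 6.11, monocytes -0.644 to 5.12, neutrophils -0.166 to 0.677, pericytes -0.0504 to 0.00797, plasmacytoid dendritic -0.0494 to 0.0425, unnamed dendritic -0.0371 to 0.259 and unnamed clusters -0.895 to 0.118. Genes that turned ranged over Cd274 -0.17 to 0.32 and Cxcl10 -0.32 to 0.11 in monocytes, Ctla4 -0.080 to 0.33 in CD4 T cells, Ctla4 -0.32 to 0.10 and Gzmb -0.36 to 0.29 in NK cells, Foxp3 -0.017 to 0.25 in regulatory T cells and H2-D1 -0.056 to 0.30 in Ptprc-low cells. Others ranged over Ifng -1.20 to 0.082 in CD4 T cells, Il1b -0.73 to 0.081 in macrophages, Il1b -0.72 to 0.28 and Nos2 -0.16 to 1.19 in monocytes, Lag3 -0.012 to 0.62 in regulatory T cells, Mki67 -0.58 to 0.037 in Ptprc-low cells and Pdcd1 -0.69 to 0.13 in NK cells. Further ones ranged over Pdcd1 -0.17 to 0.16 in regulatory T cells, Prf1 -0.60 to 0.30 in CD8 T cells, Tcf7 -0.70 to 0.41 in NK cells, Tgfb1 -0.081 to 0.45 in monocytes and Vegfa -0.39 to 0.22 in macrophages. Lists that turned had medians of cholesterol synthesis -0.32 to 0.053 in Ptprc-low cells and matrix 0.0074 to 0.48 in all cells, and that of inflammatory genes -0.82 to 0.027 in monocytes changed sign without C1 while the test kept its direction.

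On counts simulated from these libraries, 200 genes were changed, and 20 lists of 20 genes by 1.5-fold. Of 2-fold changes, 12% in CD4 T cells to 38% in macrophages were called. Of 4-fold changes, 71% in CD4 T cells to 94% in monocytes were. Changes of 2-fold or less, and some of 4-fold, in single genes can therefore be missed at this depth and spread.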
